A study of Populus trichocarpa with 6 samples.

How the data were processed

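Chromatin immunoprecipitation with an antibody against FLAG followed by sequencing (ChIP-seq) was carried out on cambium, the dividing cell layer that forms wood and inner bark, of Populus trichocarpa (black cottonwood) plants overexpressing PtrVCS2 fused to 3 copies of the FLAG peptide tag. The series holds 3 immunoprecipitated (IP) and 3 input DNA samples, described by the labels as biological replicates. Per the labels' protocols, tissue was cross-linked in 1% formaldehyde, chromatin was sheared to between 200 and 1000 bp, 20 ng of DNA entered each library, fragments of about 200 bp were selected, and 9 PCR cycles were run.

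The deposited data are 3 peak lists, 1 for each IP replicate, and the peak names in them say that each IP library was set against pooled input. Lists of the single input samples were not analysed here. The submitters' processing notes list Trimmomatic 0.33, Bowtie2 2.3.5, MACS2 2.1.0 and deepTools 3.5.1. The genome build, the annotation, the peak threshold and the treatment of duplicate reads are not given in the sources used here. The smallest −log10 p in each list lay just above 5. Each deposited list gives, per peak, a fold enrichment of IP over pooled input at the summit, a −log10 p and a −log10 q computed by the authors' peak caller, a score that is the whole part of 10 times the −log10 p, and the summit position. The files state no units, and these readings follow the layout of the caller's output. These values are the authors' own throughout. Positions are printed counted from 1.

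Gene names could not be attached to peaks. No genome sequence was used here, and the gene table at hand describes the assembly P.trichocarpa_v4.1. On 9 of 19 chromosomes peaks extended more than 100 kb past the last protein-coding gene of that table. The share of summits within 500 bp of a gene boundary was 16.3% to 16.7% in the 3 lists, and 16.5% to 17.7% after 8 shifts of all summits by 1 to 50 kb, and the unshifted share was below that of every shift in each of the 3 lists. The cause of that lower share was not tested. No build is named for the files, and because of the chromosome ends the coordinates of that table were not used. The planned comparisons that need an annotation or a sequence (shares of summits in promoters, genes near shared regions, gene lists, motifs and 6-mers) were therefore not run, and regions are named by position. The rule fixed before the data were examined for this case names the 10 shared regions with the highest mean fold over the 3 replicates.

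Peaks of the 3 lists that overlapped by at least 1 bp were merged, and a merged region with a peak in every list is called a shared region. Its fold in a replicate is that of the peak with the highest −log10 p. The number of shared regions was compared with 1000 random sets in which every peak was moved within its chromosome or scaffold, and with 1000 sets in which it was moved within its 1-Mb window (one-sided, p as the share of sets with as many regions, the observed one included). As all lists share 1 control, unchanged IP libraries were also simulated against a common pooled input in 3500447 windows, 10 times. Agreement of fold between lists was described by Spearman's rho across regions, which are not independent replicates. The ratio of IP over expected height between 2 lists was taken in regions with a −log10 q of at least 20 in the list left out of the ratio. It was given a 95% bootstrap interval over regions (1000 resamples). Regions chosen by the lists being compared could bias the ratio, which was not tested. As the folds share a denominator, rho was also computed in 1000 sets with the IP heights of each list moved among groups of 20 regions of like expected height, a test added after the data were examined. Density per chromosome was the count divided by the position of the last peak, since chromosome lengths were not used, and evenness over the 19 chromosomes was tested by a chi-square statistic against 1000 random sets. The 17 comparisons with random sets were adjusted together (Benjamini-Hochberg). Peaks on scaffolds, 45 to 66 in a list, were left out of densities.

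Read depth is not stated in the files. It was recovered in relative terms. A fold f with an added count of 1 and a Poisson upper-tail p fix a whole-number IP height (reads covering the summit after extension) and an expected height from the control. Such a pair was found to within 1e-04 of the deposited −log10 p for 99.95% of peaks in replicate 1, 100% in replicate 2 and 99.92% in replicate 3. The expected heights fell on steps of 1 control read (within 0.004 of a step) for 58.3% to 60.1% of peaks, against 0.8% by chance. The step size gives the IP reads as a share of the pooled input reads, both as kept by the caller. Reads dropped before that, such as duplicates, are not seen, and depth here means kept reads. A first, coarser search for the step returned a value 1.5 times as large for replicate 2, and was replaced by a finer search in all 3 lists. A peak is called high-input where its expected height was at least 4 times the lowest in its list. This class was defined after the data were examined, and only 31 to 76 peaks in a list lay between 3 and 5 times.

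Alternatives were a −log10 q of at least 5 or 10, the same number of peaks from each list, leaving out each replicate in turn, an overlap of at least 50% of both peaks, summits within 100 bp, and numbered chromosomes only. The count of shared regions, the peaks per list and the agreement of fold were planned. The chromosome densities, the spacing of regions and all work on recovered heights were added after the data were examined, as was leaving out high-input peaks. In simulated data the height recovery returned 100% of 2000 known heights for each replicate. The overlap count found 1003 shared regions after 1000 had been planted among randomly moved peaks, which held 4 before. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used, with Matplotlib 3.10.9 for figures.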

Results

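Peaks of FLAG-tagged PtrVCS2 over input chromatin were listed for 3 biological replicates of poplar cambium, to locate where the tagged protein is associated with the genome. Replicate 1 held 6536 peaks, replicate 2 held 10759 and replicate 3 held 9255, a mean of 8850 ± 2140 (SD, n = 3). They covered 1.85 Mb, 2.62 Mb and 3.07 Mb, with median widths of 212 bp, 183 bp and 254 bp. The median fold enrichment over pooled input was 3.03 ± 0.12 (SD, n = 3), and the highest fold in a list ranged from 14.8 to 19.0. The IP libraries had 36.2%, 34.2% and 38.1% as many kept reads as the pooled input, as recovered from the steps of the expected heights. Depth in kept reads thus differed little between replicates and was lowest in replicate 2. A median peak rested on an IP height of 44, 38 and 50 reads in replicates 1, 2 and 3, against expected heights of 13.8, 11.3 and 16.0. The shortest peaks, whose width may equal the read extension, were 113 bp, 97 bp and 126 bp. Heights count extended reads, so heights and widths cannot be compared directly between the lists.

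The first comparison asked which regions recur between the replicate lists. The 3 lists merged into 13489 regions, of which 4225 (31.3%) held a peak of every replicate, 2692 held peaks of 2 replicates and 6572 came from a single list. Shared regions had a median width of 478 bp, and their summits lay within 100 bp of each other in all 3 lists in 52.0% of cases. They took in 74.9% of the peaks of replicate 1, 47.7% of replicate 2 and 48.0% of replicate 3. Strong peaks recurred most. Of peaks with a −log10 q of at least 20, 594 of 594 in replicate 1, 610 of 614 in replicate 2 and 974 of 978 in replicate 3 lay in shared regions, whereas below a −log10 q of 5 the share was 51.4%, 22.2% and 14.1% in replicates 1, 2 and 3 (mean 29.2% ± 19.6, SD, n = 3), highest in replicate 1. Peaks found in 1 list only had a median fold of 2.80 ± 0.15, and peaks in shared regions had 3.29 ± 0.16 (SD, n = 3 each), with the higher value in shared regions in each of the 3 lists.

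**Figure D1:**
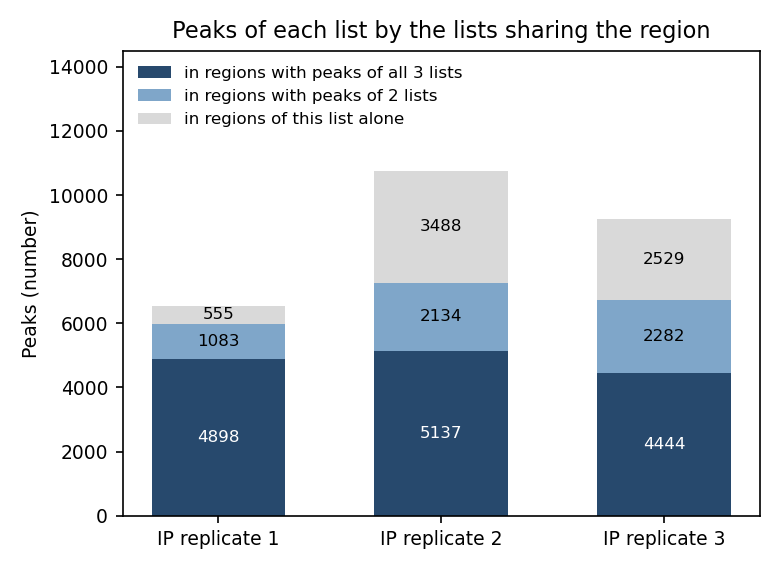
Number of peaks in each of the 3 IP lists (vertical axis), split by whether their region also held peaks of the other lists. Between 4444 and 5137 peaks of each list fall in regions shared by all 3, while peaks private to 1 list number 555 in replicate 1 and 3488 in replicate 2.

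When every peak was moved at random within its chromosome, 3.32 regions were shared on average and 10 at most in 1000 sets. Moving peaks only within their 1-Mb windows gave a mean of 6.54 and a highest value of 16. Both one-sided permutation comparisons gave p = 0.000999, the smallest that 1000 sets allow. Each pair of lists also shared more regions than any of its 1000 random sets: 4846 for replicates 1 and 2, 4876 for replicates 1 and 3 and 5879 for replicates 2 and 3, against random means of 99.6, 99.3 and 153. The lists share a control. In 10 simulations of unchanged IP libraries against a common pooled input, with the control read from 1 window alone, 1269 to 1429 windows were called per list on average and at most 1 in all 3. With a wider control as a lower bound, 26.1 to 48.6 were called per list and none in all 3. These simulations used 1 uniform control level, 1.89 times the lowest, and cover counting error only. The count depended on how strictly a shared region was defined. It was 1355 with a −log10 q of at least 10, 2331 with an overlap of 50% of both peaks for every pair, and 2359 with summits within 100 bp.

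Fold enrichment was correlated between replicates across shared regions, which are not independent replicates. Across the 4225 regions Spearman's rho was 0.72 between replicates 1 and 2, 0.76 between 1 and 3, and 0.74 between 2 and 3 (mean 0.739 ± 0.020, SD of 3 pairs). The folds share a control, and with IP heights moved among regions of like expected height, rho was 0.28 to 0.30 on average and 0.34 at most (1000 sets per pair, permutation p = 0.000999 for each pair). Without high-input regions rho was 0.64, 0.69 and 0.67, against 0.13 at most with moved heights (permutation p = 0.000999). Over the shared regions, the median of the mean folds was 3.35. The standard deviations between replicates had a median of 0.355 and a mean of 0.416. A mean fold of at least 5 was reached by 464 regions (11.0%), and a mean of at least 10 by 11. Recovered IP heights varied less between the lists than independent Poisson counts would. Their mean dispersion index was 0.565 in the 3836 shared regions without high input, where independent Poisson counts would give 1. That reference allows for neither a limit on kept reads nor the choice of regions called in every list, so variation below counting error was not shown. The cause was not tested, and the spread between replicates may be understated. In the 941 shared regions without high input and with a −log10 q of at least 20 in replicate 3, the recovered IP height over the expected height was higher in replicate 2 than in replicate 1 in 67.4% of cases, with a median ratio of 1.08 (95% bootstrap interval over regions 1.07 to 1.09).

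The region with the highest mean fold lay on chromosome 18, from 9352098 to 9352548. Its fold was 16.2, 19.0 and 14.8 in replicates 1, 2 and 3, a mean of 16.7 ± 2.1 (SD, n = 3), and its summits fell within 14 bp of each other. Its expected height was the lowest of its list in every replicate, and its IP heights were 131, 128 and 138. The region on chromosome 3 from 11685046 to 11686007 followed with a mean fold of 13.1 ± 1.9. Next came chromosome 9 from 8320530 to 8321459 with 12.8 ± 0.90 and higher IP heights of 187, 150 and 194, and chromosome 6 from 4343604 to 4344951 with 12.5 ± 0.89. A region on chromosome 2 from 2913314 to 2913848 had a mean fold of 12.2 ± 1.2. It was the only one of the 10 whose summits spread over more than 40 bp, at 174 bp. The region on chromosome 12 from 13867194 to 13867949 had 12.1 ± 2.4, the largest standard deviation among the 10, with folds from 9.42 in replicate 3 to 14.1 in replicate 2. The remaining 4 were on chromosome 10 from 21893858 to 21894715 (10.9 ± 0.64), chromosome 4 from 15548891 to 15549175 (10.8 ± 1.8), chromosome 6 from 8101735 to 8102578 (10.6 ± 0.23) and chromosome 3 from 18258132 to 18259421 (10.4 ± 0.56). All errors are SD with n = 3. With heights corrected for a limit of 1 kept read per position and strand, a modelled value, IP over expected height rose 1.40 to 1.82 times at these regions, by more than 1.5 times at 6 of the 10, and the region on chromosome 9, at 24.9 ± 2.8, came above that on chromosome 3, at 23.6 ± 5.0. The genes at these positions are not reported, because no annotation of the build was used here. Differences between neighbouring ranks lay mostly within the replicate spread, and the ranking of these 10 is not a tested order.

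**Figure D2:**
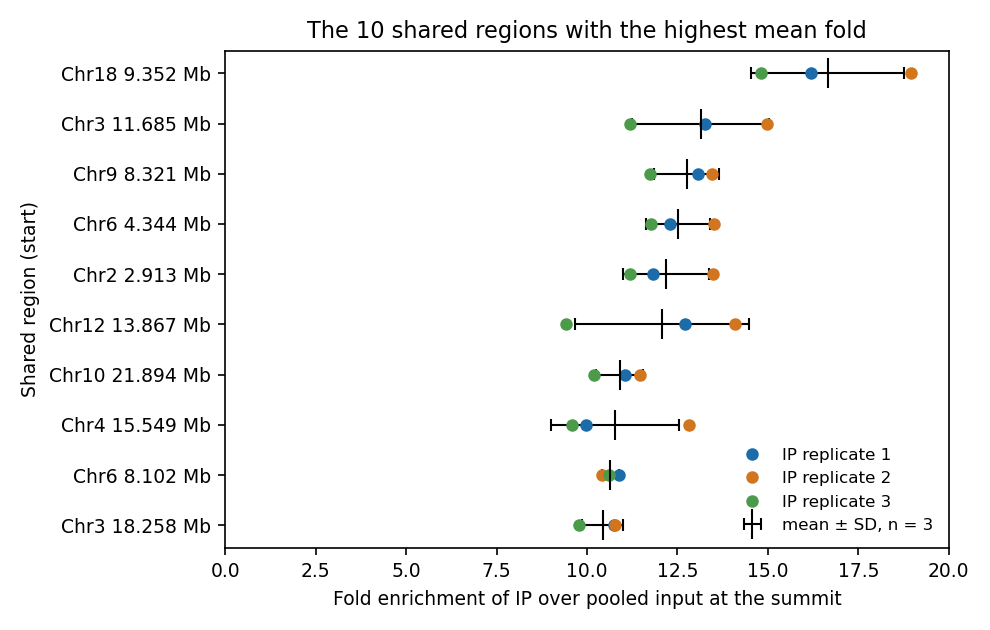
Fold enrichment of IP over pooled input at the summit (horizontal axis) for the 10 shared regions with the highest mean fold, named by chromosome and start in Mb (vertical axis). Coloured points are the 3 replicates and black bars the mean ± SD. The region on chromosome 18 stands at 16.7 and the tenth, on chromosome 3, at 10.4. For the region on chromosome 18 the expected height was the lowest of each list, which may be a lower bound and not the local input.

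A class of peaks lay where the input itself was high. Expected heights at peaks had a median of 1.92 ± 0.02 times the lowest value of their list (SD, n = 3), but 538 peaks of replicate 1, 698 of replicate 2 and 420 of replicate 3 had at least 4 times that value. Their median fold was 2.05 ± 0.18, against 3.08 ± 0.12 for all other peaks (SD, n = 3 each). A threshold on p lets smaller folds pass where the expected height is higher, so the calling partly set the direction of this difference. The lowest fold among the other peaks was 2.04, 1.97 and 1.90 in replicates 1, 2 and 3. In the whole lists it was 1.54, 1.64 and 1.47. Part of the high-input peaks lay in a few short stretches, which are named here after their values were seen. On chromosome 13, 109 of these peaks (37, 41 and 31 in replicates 1, 2 and 3) lay between 14824277 and 14882221. On chromosome 2, 108 (39, 34 and 35) lay between 18348884 and 18389694, and on chromosome 15, 36 lay between 6322437 and 6332106. Of the shared regions, 389 (9.21%) were of this class. With high-input peaks left out, 3834 regions were shared. The highest IP height in each list was exactly 2 times its shortest peak width, 226 reads for 113 bp, 194 for 97 bp and 252 for 126 bp. The 10 regions with the highest mean fold reached 55.9% to 79.0% of that height, on average over the replicates.

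**Figure D3:**
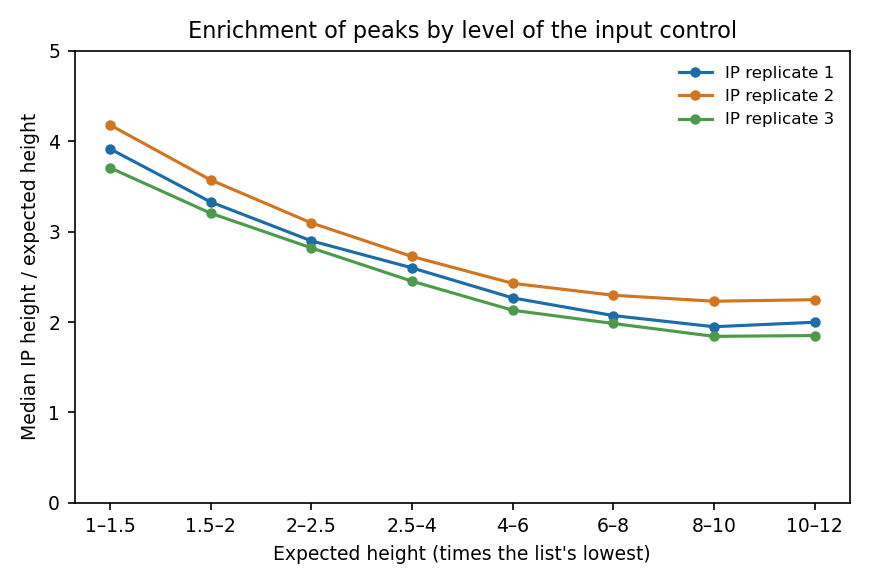
Median IP height divided by expected height (vertical axis) for peaks grouped by their expected height as a multiple of the lowest in their list (horizontal axis), 1 line per IP replicate. The ratio is 3.71 to 4.18 in the lowest group and 1.85 to 2.25 in the highest. The threshold on p lets smaller ratios pass at higher expected heights, which partly sets this fall.

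The last comparison concerned where along the genome shared regions fell. They were unevenly spread over the 19 chromosomes. Without high-input regions, chromosome 9 held 15.3 per Mb, chromosome 8 held 13.5 and chromosome 10 held 12.1, while chromosome 17 held 6.03 and chromosome 19 held 4.10. The overall value was 9.75 per Mb. The peaks of the single lists followed, with 34.9 ± 9.6 per Mb on chromosome 9 and 9.14 ± 1.75 on chromosome 19 (SD, n = 3, all peaks). In every list the density was higher on chromosome 9 than on chromosome 19. The chi-square statistic over chromosomes was 194, and 49.3 at most in 1000 random sets (one-sided permutation p = 0.000999, the smallest possible). Counting neighbours within 5 kb as 1 left the statistic at 137, against 60.8 at most in random sets (permutation p = 0.000999). The 17 comparisons with random sets all gave this p, and Benjamini-Hochberg adjustment left it at 0.000999 (permutation).

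**Figure D4:**
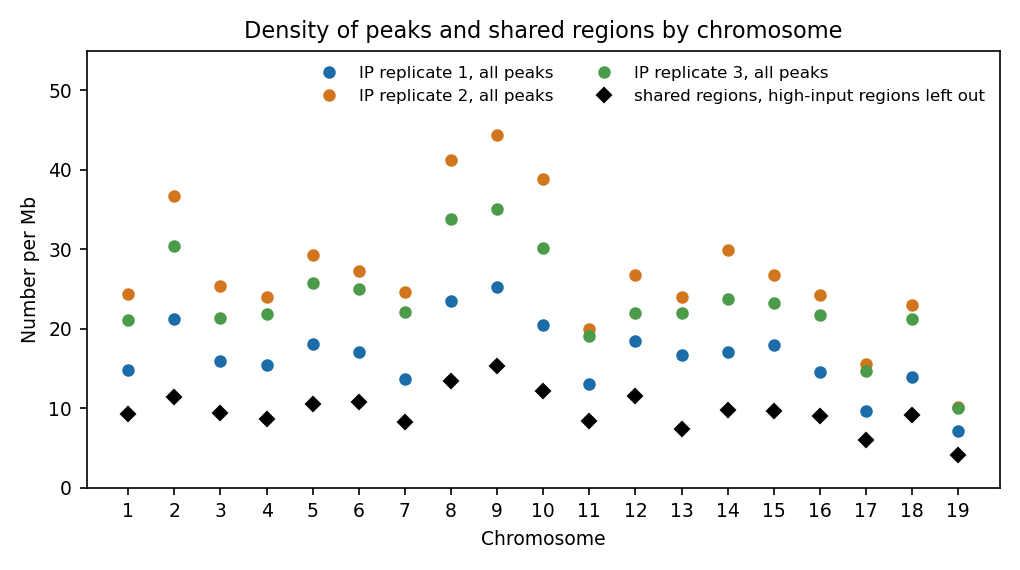
Number per Mb (vertical axis) of all peaks in each IP replicate (coloured points) and of shared regions with high-input regions left out (black diamonds) on each of the 19 chromosomes (horizontal axis). Shared regions range from 4.10 per Mb on chromosome 19 to 15.3 on chromosome 9, and the 3 lists are lowest on chromosome 19 as well.

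Shared regions also lay close together. Without high-input regions, 37.2% had another shared region within 5 kb, against 9.27% on average and 11.6% at most in random sets (permutation p = 0.000999). The windows and stretches named next were chosen after their values were seen, and high-input regions are left out of them unless stated. The densest 1-Mb window was on chromosome 10 from 18000001 to 19000000, with 39 shared regions and 74.7 ± 20.6 peaks outside the high-input class (SD, n = 3). It was followed by chromosome 9 from 9000001 to 10000000 with 32. No window of the random sets held more than 27. At the other end, 23 of 401 windows held no shared region, against 1.19 on average and 4 at most in random sets. The longest stretch without a shared region ran on chromosome 14 from 14799565 to the last peak at 18646073, over 3.85 Mb, and held 10 shared regions of the high-input class. The next were 2.93 Mb each, on chromosome 19 from 4745655 to 7677109 and on chromosome 6 from 13851244 to 16782091. Outside the high-input class, the 3 stretches held 0, 0 and 2 peaks, 1, 2 and 4 peaks, and 0, 3 and 1 peaks, in replicates 1, 2 and 3. A window on chromosome 13 from 14000001 to 15000000 had 52 shared regions, the most of any window when high-input regions were counted, and 7 without them.

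**Figure D5:**
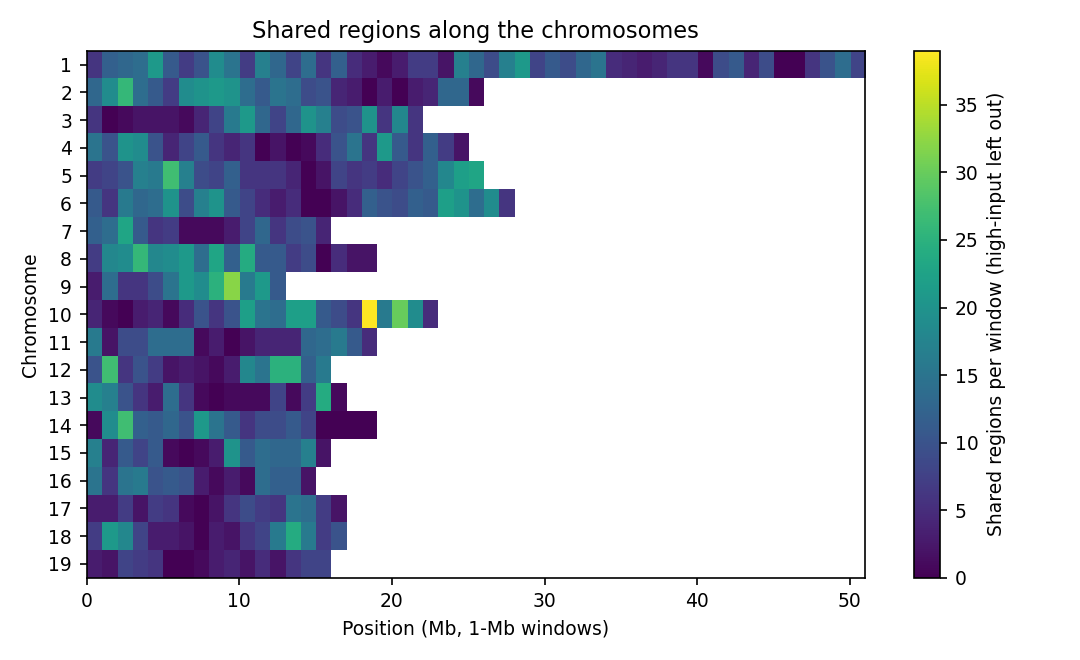
Shared regions per 1-Mb window, high-input regions left out (colour), by position in Mb (horizontal axis) on the 19 chromosomes (vertical axis); the last window of a chromosome is shorter. The brightest window, with 39 regions, is on chromosome 10 at 18 Mb, and 23 of the 401 windows hold none.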

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

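Leaving out high-input peaks, and the tests of density and spacing, were chosen after the data were examined. Requiring a −log10 q of at least 10 lowered the mean number of peaks per list to 2786 and the shared regions to 1355. A requirement that every pair of peaks overlap by 50% of both left 2331 shared regions, and summits within 100 bp left 2359. The other alternatives that kept 3 lists, high-input peaks left out among them, kept the count of shared regions within 1.5 times of 4225. When 1 replicate was left out, the pair of lists that remained shared 4846 to 5879 regions. That is a looser definition, so it was no test of the count of 4225. The mean rho of fold between lists was 0.799 with a −log10 q of at least 10, 0.760 with the same number of peaks from each list, 0.847 with the 50% overlap and 0.838 with close summits. It was 0.664 without high-input peaks. When 1 replicate was left out, rho of the pair that remained was 0.681 to 0.734, over the regions shared by that pair. The cause of these shifts was not tested. Chromosome 9 stayed the densest and chromosome 19 the sparsest in 9 of 9 alternatives that could move them, with a ratio of 3.28 to 3.86, and the share of shared regions with a neighbour within 5 kb was 20.7% to 47.7%, above random placement each time. Leaving the added count of 1 out of the fold moved the mean of 6 of the 10 named regions by more than their SD. Leaving out 1 of 3 replicates cannot move a mean by its SD, so it was no test of these folds by that measure. Planned comparisons with promoters, genes, gene lists, motifs and 6-mers were not run. No paired analysis was possible because the control of every list was the pooled input, and single inputs were not analysed here. The lists hold only peaks past the caller's threshold, so a region missing from a list was not shown to be unbound at this depth.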

Other observations

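All tests in this part were chosen after the results they bear on had been seen. Without high-input regions, the median of the mean folds was 3.65 on chromosome 17, which had 6.03 shared regions per Mb, 3.39 on chromosome 9, with 15.3 per Mb, and 3.33 on chromosome 19, with 4.10 per Mb. These are medians over regions, and their differences were not tested. With high-input regions counted, scaffolds outside the chromosomes held 31 shared regions on 18 scaffolds. Of the 3836 shared regions outside the high-input class, 3823 lay on chromosomes, so many of the 31 were high-input regions.

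Peaks at high-input sites may be products of a limit on reads: where both libraries reach a ceiling, the deeper pooled input is scaled down and a fold of 2.74, 2.90 or 2.61 follows in replicates 1, 2 and 3 with no enrichment. In each list the IP height stopped at exactly 2 times the shortest peak width, and the expected height stopped at that value times the size of 1 control read, which is what a limit of 1 kept read per position and strand would give if the shortest width equals the read extension. The 448 peaks whose control was at 90% or more of the ceiling had a median IP height of 0.975 ± 0.038 times the one modelled with no enrichment (SD, n = 3), although sites far below the modelled height would not have been called. The other high-input peaks numbered 1208. As a mean over the 3 lists, 26.3% ± 7.9 of them would pass a −log10 p of 5 in the model (SD, n = 3). Their median IP height was 1.46 ± 0.15 times the modelled one (SD, n = 3). For these peaks the ceiling and true binding cannot be told apart, as the model leaves out that a summit is the highest of many positions. Corrected under this model, the IP over expected height of the region on chromosome 18 at 9352098 would be 27.8 ± 6.0 in place of 18.9 ± 2.9 (SD, n = 3). There the model treats an expected height that may be a lower bound as a height of reads. For the region on chromosome 9 at 8320530 the value would be 24.9 ± 2.8 in place of 13.7 ± 1.2 (SD, n = 3). That is above 23.6 ± 5.0 for the region on chromosome 3 at 11685046 (SD, n = 3).

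Replicate 2 had the most peaks but not the most reads kept by the caller. Its kept IP reads were 0.944 times those of replicate 1 and 0.898 times those of replicate 3, which argues against more kept reads as the cause. The number sequenced before any removal of duplicates is not known. Stronger enrichment at the same sites would give replicate 2 a higher IP over expected height. In shared regions with a −log10 q of at least 20 in the list left out, its median ratio was 1.08 to replicate 1 (941 regions, 95% interval 1.07 to 1.09). To replicate 3 it was 1.02 (560 regions, 1.01 to 1.04). These ratios do not decide the question. Each side is 1 library, the intervals resample regions, and the heights were not corrected for the read ceiling. Peaks with a control at 90% or more of that ceiling had their highest IP over expected height in replicate 2. There the median was 2.26, against 2.01 and 1.84 in replicates 1 and 3. The ceiling gives this order with no enrichment, with folds of 2.90 in replicate 2, 2.74 in replicate 1 and 2.61 in replicate 3. These peaks therefore say nothing about stronger enrichment. Replicate 2 also had the shortest peaks (97 bp at least). If a shorter read extension raised the ratio, replicate 3, with 126 bp, should fall below replicate 1. It did not, with a median ratio of 1.02 to replicate 1 (550 regions, 1.01 to 1.04). This too sets 1 library against 1, with an interval over regions alone, so a difference this small leaves read extension open. No biological explanation was tested, since the labels separate the replicates by number alone.

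The uneven placement of shared regions was not produced by high-input sites, since the ratio of the densest to the sparsest chromosome was 3.73 without them. Uniform random placement along the chromosomes is also argued against, since 37.2% of these regions had another within 5 kb and 11.6% was the most in random sets. The sets say nothing about placement limited to part of the genome. Of all shared regions, high-input ones included, 1160 held more than 1 peak of a list. Whether neighbouring regions are parts of 1 broader site was not tested. Gene density, open chromatin, and repeats in which reads cannot be placed remain possible explanations that were not tested, because no genome or annotation of the build was used. Whether tagged PtrVCS2 or general accessibility of chromatin sets these positions stays open too, as an IP from plants without the tag was not analysed here.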
